A study of Homo sapiens with 6 samples.

How the data were processed

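RNA of 3 APTX knockout and 3 control U2OS cultures was labelled from an oligo-dT primer with biotin and hybridised to 1-colour Illumina beadchips, per the labels' protocols. The deposited table holds a signal intensity and a detection p-value for each of 47231 probes and each array, exported with GenomeStudio 2011.1 per the submitters' processing notes. The intensity values were on a linear scale with unequal array medians, and no background subtraction or normalization was seen in them. The detection p-value compares a probe with the array's negative control probes. The value table of the series holds the authors' processed values, a score: each column lay within 0.021 of the Z-score of the log signal of the same array, and at least 0.71 from that of any other array at the largest difference. Its medians were -0.44 on 5 arrays and -0.42 on control replicate 1. Its scale is thus SD units per array, its centring is the array mean, and higher values mean more signal; the log base and the software are not given in the sources used here.

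Samples were grouped by their labels. Probes were named through the platform annotation given with the series, with symbols updated by gene identifier from a RefSeq table of the assembly GRCh38.p14. In all, 30113 probes had 1 gene (39 of these kept the platform's symbol), 8 had several and 17110 had none listed, and those of the last 2 kinds were left unnamed. The files name no genome build, so chromosomes and gene order, but no coordinates, were taken from that table.

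Intensities were background corrected with limma 3.58.1 in R 4.3.3 by a normal-exponential model whose negative control mean and SD were inferred from the detection p-values (offset 16), quantile normalized and log2 transformed. A probe was tested when its detection p was under 0.01 on all 3 arrays of at least 1 group, which left 16008 probes. Each gene was represented by its tested probe with the highest mean over the 6 arrays. Knockout was compared with control by lmFit and eBayes with group as the only term, two-sided, and Benjamini-Hochberg adjustment ran over all tested probes, with a threshold of 0.05. Where a probe was not well above background on any array of a group, the fold is a bound, computed against the lowest level among detected probes of each array, or the probe's own level where higher, from means of normalized log2 values.

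Gene lists were tested with limma's camera at an inter-gene correlation of 0.01 on the representative probes, adjusted over the 38 lists with at least 5 tested members; 39 lists were written. The tests, lists and the rule for named genes were fixed before the data were examined. The rule names APTX and OPA1, the 12 largest rises and 12 largest falls among called genes whose groups do not overlap and whose probe is detected on all arrays of the higher group, up to 2 rising and 2 falling called members of each list, and the tested genes around APTX; placeholder symbols were passed over. For length, some of these genes were left unnamed. Which ones was decided after their values were seen, and they are mostly list members whose call was lost in an alternative, so the genes named are steadier than the rule's full set. Totals over alternatives are therefore given for all genes of the rule's first 3 parts, named or not, together with the other genes whose levels are given. APTX and OPA1 are not in these totals, and their alternatives are given on their own. Of 3090 tested probes without a gene name, 980 changed.

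The steps were tested on simulated arrays with 200 genes changed by known folds among 13584 tested. The fit called 37.3% of genes changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 4-fold in the right direction, and 15 of 13363 unchanged genes. Camera called the 1 list that had been shifted and no other. The simulated noise was independent between genes, and a far smaller share of genes was changed than in the real data. These rates therefore need not hold for the real arrays, and false list calls from correlated genes could not appear. Median estimates were 0.93 for a true log2 change of 1 and 1.89 for 2.

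Alternatives covered the background correction and its offset, the scaling between arrays, the authors' Z-scores (put on a log2 scale by the mean SD of the arrays' log2 signals), the filter on dim probes, the variance model, array weights, the replicate number as a block, each array left out in turn, the mean of all probes of a gene, a size threshold of 1.2-fold, and other set tests. Arrays were left out after normalization and filtering on all 6. Slide as a block was not run, since neither columns nor labels give the slide. Probe-level control data, scan dates and the sequence of the nicked site were not used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.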

Results

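The series measured RNA from U2OS cells, a human osteosarcoma line, in which the gene for aprataxin (APTX) had been disrupted with a pair of CRISPR nickases, and from control U2OS cells. Aprataxin removes the adenylate groups that abortive ligation leaves on broken DNA ends. Its loss causes an inherited cerebellar ataxia. The labels give 3 knockout and 3 control samples as biological replicates, and each was hybridised to a 1-colour Illumina beadchip with 47231 probes. They say that single-cell colonies were grown and that the disruption was checked by PCR and Western blot. They do not say whether the 3 knockout samples came from separate colonies, so the p-values measure the spread between these samples only. The deposited signal had a median between 141 and 152 on the knockout arrays and between 105 and 137 on the control arrays. Control replicate 1 was the dimmest array, with a mean signal of 340 against 489 to 640 on the other arrays. Between 32.6% and 36.3% of the probes had a detection p under 0.01 on an array. Arrays of the knockout group correlated at 0.985 to 0.993 and those of the control group at 0.980 to 0.987, while arrays of different groups correlated at 0.924 to 0.937. The number of arrays limits the precision of every value. Differences are given as knockout minus control on the log2 scale, with the SE of the limma fit and n = 3 arrays per group.

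The knocked-out gene came first. The brighter APTX probe read 9.52, 9.57 and 9.55 on the knockout arrays and 9.64, 9.45 and 9.73 on the control arrays, a difference of -0.06 ± 0.13 (95% interval -0.36 to 0.24, adjusted p = 0.75). The other APTX probe differed by -0.05 ± 0.15 (adjusted p = 0.81). A frameshift can leave the amount of mRNA as it was, and the place of either probe relative to the nicked site is not given in the sources used here, so these probes do not check the labels. The 16 tested genes of the chromosome 9 region around APTX had a median difference of 0.02. In it PRSS3, which encodes a trypsin, rose by 2.45 ± 0.26 and NOL6 fell by 0.73 ± 0.15. NFX1 fell by 0.56 ± 0.16 (adjusted p = 0.022), a call that was lost without knockout replicate 1 or 3 or control replicate 1 or 3 (-0.44, -0.59, -0.47 and -0.57). It was also lost, at -0.56, in the replicate block (adjusted p = 0.059) and without a filter on dim probes (adjusted p = 0.054). With median centring NFX1 and NOL6 read -0.27 and -0.47, neither past the test, or -0.54 and -0.73 relative to the median of all genes. The other 13 genes did not pass the test. Over all 16 genes, 1 was higher and 2 were lower adjusted over the list alone, and the camera adjusted p was 0.92.

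The series title asks about OPA1, the inner membrane GTPase that fuses mitochondria and shapes their cristae. OPA1 was lower in the knockout cells. Its tested probe read 6.20 ± 0.24 (SD, n = 3) in knockout and 7.29 ± 0.22 (SD, n = 3) in control cells, a fall by 1.10 ± 0.17 or 2.14-fold (95% interval of the difference -1.48 to -0.72, adjusted p = 0.0011). All 3 knockout values lay below the 3 control values. The probe was dim: the deposited signal was 178 to 219 on the knockout arrays and 183 to 257 on the control arrays, so the groups overlapped before normalization. The size depended on the background step, and the difference was -0.56 (adjusted p = 0.0017) without background correction and -0.52 in the deposited Z-scores on a log2 scale. The second OPA1 probe was not well above background on any array and was not tested. It read 4.83 in knockout and 4.67 in control cells, a difference of 0.17 in the other direction, with the groups apart. At that level it does not measure OPA1, so the fall rests on 1 dim probe. The genes next to OPA1 on chromosome 3 were lower too: of the 40 tested genes nearest to it in gene order, 28 fell, 0 rose and 12 did not pass the test, with a median difference of -0.70. Their median was -0.46 without background correction and -0.43 in Z-scores.

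**Figure D1:**
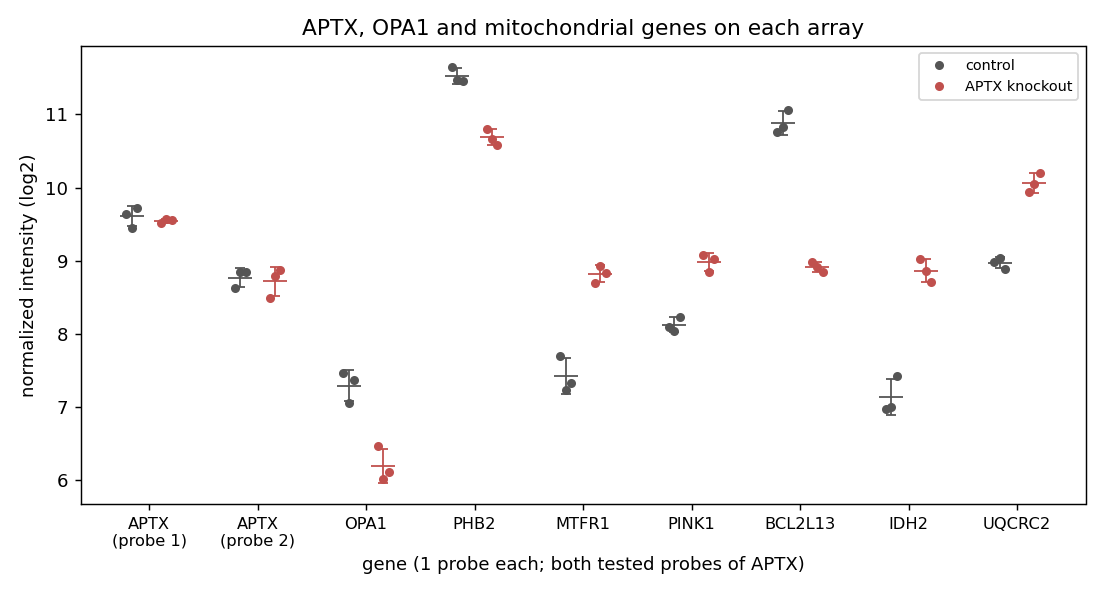
Normalized intensity (log2) of both tested APTX probes and of 7 other genes on each array, with control arrays in grey and APTX knockout arrays in red. Points are arrays, horizontal lines are means and bars are SD (n = 3); the APTX values of the groups overlap, and OPA1 reads 6.20 in knockout against 7.29 in control cells.

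Across the transcriptome, 3733 of 10013 genes tested changed (37.3%), 1856 higher and 1877 lower in the knockout cells. A change of at least 2-fold was seen for 991 genes, of which 492 were higher and 499 lower. The groups did not overlap for 5090 genes (50.8%), where chance gives 10%. The largest rises included MAGEA10, a cancer-testis antigen, which was 35.2-fold higher (5.14 ± 0.15). For the other 11 genes named by the same rule the probe was not well above background on any control array, so that only a bound can be given. IL13RA2, a decoy receptor for interleukin-13, was at least 17.1-fold higher, the amino acid transporter SLC7A10 at least 16.3-fold and the peptide precursor NMB at least 10.2-fold. ADD2 and RAC2, which act on the actin cytoskeleton, were at least 9.99-fold and 9.97-fold higher. The proteoglycan GPC5, the chondroitin sulfotransferase CHST15, the receptors IFNLR1 and IL17RB, the smooth muscle protein CNN1 and CCDC62 were at least 4.27-fold to 7.42-fold higher.

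The largest fall was that of DHRS2, a mitochondrial and nuclear reductase, which was at least 209-fold lower and not well above background in the knockout cells (5.26 ± 0.14 against 13.59 ± 0.11, SD, n = 3). The GAGE genes, cancer-testis antigens encoded by near-identical copies on the X chromosome, fell together. GAGE12G was at least 57.7-fold lower, GAGE4 at least 59.8-fold and GAGE12B at least 18.8-fold. Their probes may read more than one copy, so the number of genes that fell is uncertain. The 40 tested genes nearest to GAGE12B and GAGE12G, other GAGE genes included, had medians of -0.58 and -0.50. The secreted protease KLK6 was at least 32.0-fold lower, TRIML2 at least 15.2-fold and the homeobox gene HOXB2 at least 15.6-fold. CRYBA4, a lens crystallin, was detected on every array and fell by 5.25 ± 0.17. Probes of 202 genes were detected on all 3 knockout and no control array, and those of 171 genes on all 3 control and no knockout array.

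The split into higher and lower depended on the scaling. When each array was centred on its median in place of quantile normalization, the median of all genes moved to 0.26, and 2219 genes were called higher and 678 lower. That centre was the median of all 47231 probes, of which 32.6% to 36.3% were detected on an array. It thus lay among undetected probes, and differences in brightness between the detected probes of the arrays could remain. The number of genes changed at least 2-fold was 383 without background correction. Among 2427 genes with several tested probes, 19 had probes called in opposite directions.

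**Figure D2:**
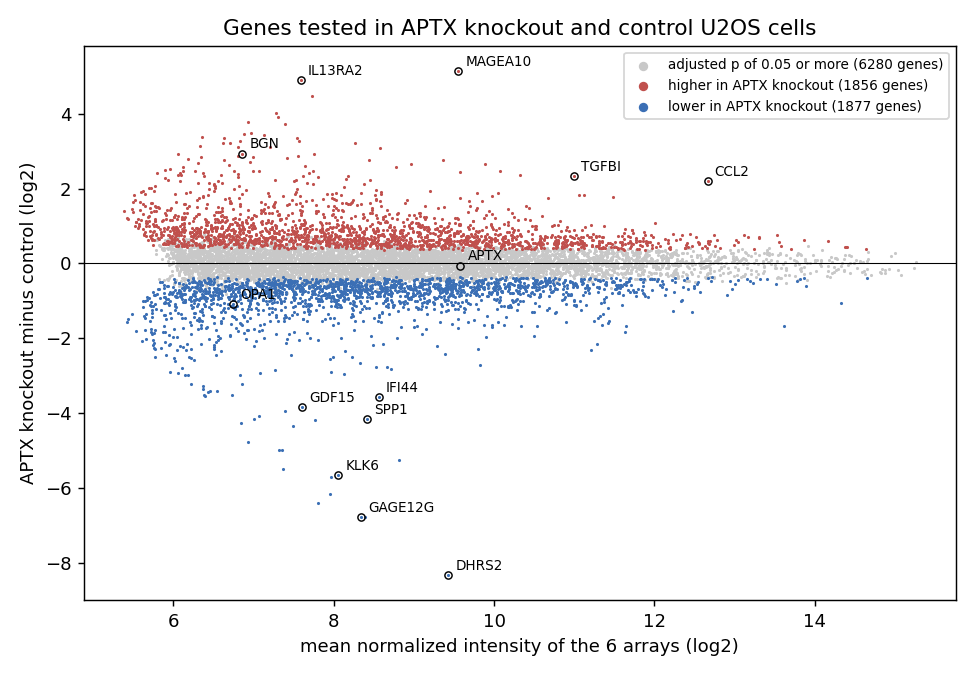
Difference between APTX knockout and control cells (log2) against the mean normalized intensity of the 6 arrays (log2), one point per gene, red where higher and blue where lower with an adjusted p under 0.05. Named genes are circled; 1856 genes were higher and 1877 lower, APTX lay at -0.06 and DHRS2 at a fitted difference of -8.33.

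The genes of mitochondrial fusion and fission went both ways. Of 25 tested, 6 rose and 6 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.92). Beside OPA1, the prohibitin PHB2, which stabilises long OPA1 forms, fell by 0.84 ± 0.13. OPA1 lies in the lowered end of chromosome 3, where the 40 tested genes nearest to it had a median of -0.70. MFN1 (-0.80, limma adjusted p = 0.0037) and PARL (-0.64, limma adjusted p = 0.0050) lie on the same chromosome, in the lowered stretch around MAP6D1 (median -0.77). The falls of OPA1, MFN1 and PARL therefore need not be separate changes of the pathway. The fission regulator MTFR1 rose by 1.40 ± 0.16. The call of PHB2 was lost with median centring, where it read -0.55, or -0.82 relative to the median of all genes, and the 40 tested genes nearest to PHB2 had a median of -0.60. Among 15 genes of the contact site and cristae complex 3 rose and 0 fell (3 and 0 adjusted over the list alone; adjusted p = 0.32), with MTX3 at 0.82 ± 0.14 and CHCHD6 at 0.75 ± 0.15. The 40 tested genes nearest to MTX3 had a median of 0.73. Of 26 genes that maintain mitochondrial DNA, 6 rose and 5 fell (6 and 5 adjusted over the list alone; adjusted p = 0.80), and POLG2, the accessory subunit of its polymerase, rose by 0.64 ± 0.15.

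Regulators of mitochondrial biogenesis were lower where they changed. Of 15 tested, 5 fell and 0 rose (5 and 0 adjusted over the list alone; adjusted p = 0.25). PPARGC1A, the coactivator PGC-1alpha, fell by 0.89 ± 0.28 (adjusted p = 0.0345) and was detected on 1 of the 3 knockout arrays. Its call was lost in the Z-scores (-0.32), in the authors' values (-0.31) and without a filter on dim probes (-0.89). The same happened when knockout replicate 2 or 3 or control replicate 1 or 3 was left out, with values of -0.84, -0.67, -0.69 and -0.81. Of 20 mitophagy genes, 3 rose and 8 fell (3 and 9 adjusted over the list alone; adjusted p = 0.30). The receptor BCL2L13 fell by 1.96 ± 0.14 and the kinase TBK1 by 1.15 ± 0.13, while the kinase PINK1 rose by 0.86 ± 0.14. CALCOCO2, detected on 2 of the 3 control arrays, rose by 1.22 ± 0.14.

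Genes of the respiratory chain rose more often than they fell, without a shift of any list that passed the test. Complex I had 6 rising and 2 falling members of 30 (2 and 1 adjusted over the list alone; adjusted p = 0.39), with NDUFS3 up by 0.64 ± 0.13. Complexes II to IV had 4 rising and 0 falling members of 22 (4 and 0 adjusted over the list alone; adjusted p = 0.33), among them the complex III subunits UQCR11 at 1.11 ± 0.14 and UQCRC2 at 1.09 ± 0.13. ATP synthase had 2 rising and 1 falling member of 18 (0 and 1 adjusted over the list alone; adjusted p = 0.92); the ring subunit ATP5MC2 fell by 0.77 ± 0.13 and with median centring read -0.49, not past the test, or -0.75 relative to the median of all genes. No tested probe was named for a transcript of the mitochondrial genome. Of 22 genes of the tricarboxylic acid cycle, 10 rose and 1 fell (10 and 2 adjusted over the list alone; adjusted p = 0.13), led by IDH2, the mitochondrial NADP-dependent isocitrate dehydrogenase, at 1.73 ± 0.16, and DLD at 1.26 ± 0.22.

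Of 73 mitochondrial ribosomal protein genes, 13 rose and 5 fell (10 and 3 adjusted over the list alone; adjusted p = 0.39). MRPS27 rose by 1.12 ± 0.14 and MRPL47 fell by 0.99 ± 0.16, and the 40 tested genes nearest to each had medians of 0.65 and -0.63. Protein import had 4 rising and 4 falling members of 25 (4 and 4 adjusted over the list alone; adjusted p = 0.92). TOMM6 rose by 0.76 ± 0.13, TIMM17B fell by 0.99 ± 0.17, and DNAJC19, detected on 1 of the 3 knockout arrays, fell by 1.26 ± 0.22. The nearest 40 genes had a median of 0.56 for TOMM6, -0.87 for TIMM17B and -0.65 for DNAJC19. Chaperones and proteases had 3 and 3 of 16 (3 and 3 adjusted over the list alone; adjusted p = 0.93), with the protease HTRA2 up by 0.73 ± 0.13. Fatty acid oxidation had 5 rising and 3 falling of 21 (5 and 3 adjusted over the list alone; adjusted p = 0.92), and the carnitine carrier SLC25A20, not well above background in control cells, was at least 1.71-fold higher. Coenzyme Q synthesis had 3 and 3 of 11 (5 and 3 adjusted over the list alone; adjusted p = 0.69), with COQ2 up by 0.85 ± 0.16. NAD metabolism had 4 rising and 3 falling of 17 (5 and 4 adjusted over the list alone; adjusted p = 0.92), with NAMPT, the rate-limiting enzyme of the salvage pathway, up by 0.92 ± 0.19 and its 40 nearest genes at a median of 0.50. Glycolysis had 5 and 3 of 21 (5 and 4 adjusted over the list alone; adjusted p = 0.92); ALDOC fell by 2.83 ± 0.16 and the glucose transporter SLC2A3 by 1.18 ± 0.16, while ALDOA rose by 0.79 ± 0.15. The 40 genes nearest to SLC2A3 had a median of -0.59.

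**Figure D3:**
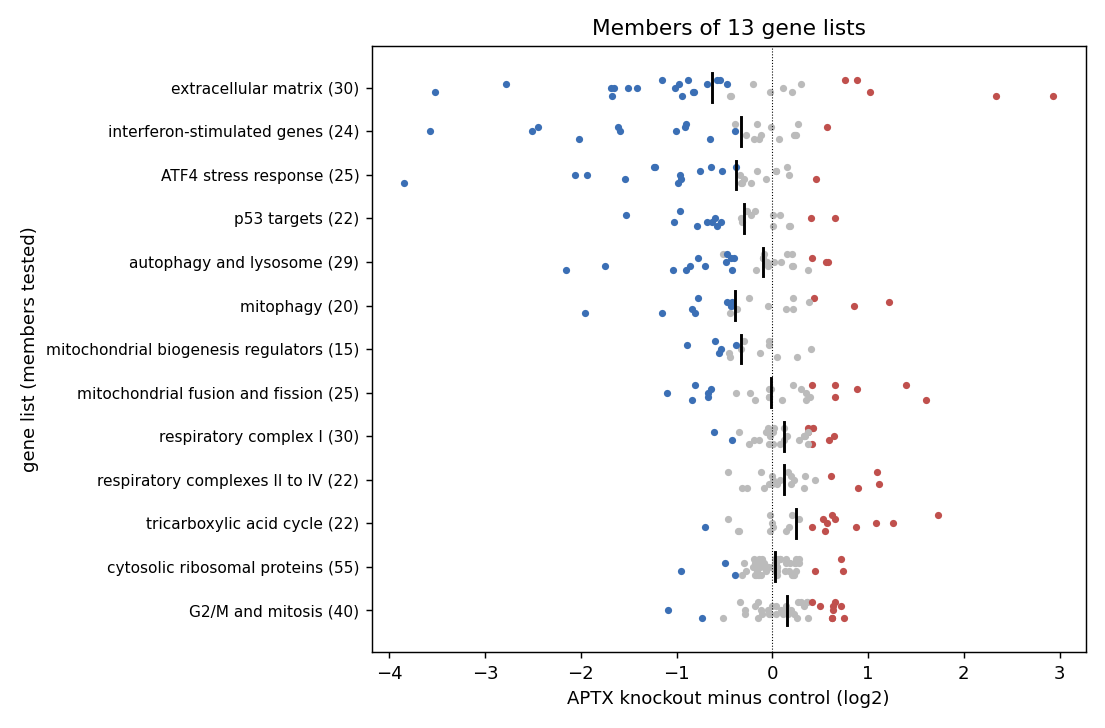
Difference between APTX knockout and control cells (log2) of every tested member of 13 gene lists, one point per gene, red where higher, blue where lower and grey where the adjusted p was 0.05 or more. Black bars mark each list's median and the number of members tested stands in parentheses; the median was -0.63 for the extracellular matrix and 0.24 for the tricarboxylic acid cycle.

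Of the 38 lists with at least 5 tested members, 3 shifted down against the other genes in camera with its preset correlation, and the others did not pass. None of the 3 calls held with an estimated correlation, which gave an adjusted p = 0.52 for the ATF4 stress response, 0.52 for interferon-stimulated genes and 0.73 for the extracellular matrix, and 4 of the 10 splits of the arrays into 3 and 3 gave at least 3 lists. The first was the ATF4 stress response, with 13 of 25 members lower and 1 higher (14 and 1 adjusted over the list alone), a median of -0.38 and a camera adjusted p of 0.00027. GDF15, a stress-induced cytokine, fell by 3.84 ± 0.17 and was detected on 1 of the 3 knockout arrays, and DDIT3, the transcription factor CHOP, fell by 2.06 ± 0.14. The 40 tested genes nearest to DDIT3 had a median of -0.44. The second was that of interferon-stimulated genes, with 11 of 24 lower and 1 higher (11 and 1 adjusted over the list alone), a median of -0.33 and an adjusted p of 0.0037. IFI44 fell by 3.58 ± 0.17 and IFIT2 by 2.51 ± 0.15, while the exonuclease ISG20 rose by 0.57 ± 0.15. The third was the extracellular matrix, with 18 of 30 lower and 5 higher (19 and 5 adjusted over the list alone), a median of -0.63 and an adjusted p of 0.013. COL6A3 fell by 2.78 ± 0.22 and COL3A1, not well above background in the knockout cells, was at least 4.76-fold lower. The proteoglycan BGN was at least 5.21-fold higher and TGFBI rose by 2.33 ± 0.13. With median centring the medians of the ATF4, interferon and matrix lists were -0.15, -0.04 and -0.36, or -0.41, -0.31 and -0.62 relative to the median of all genes. The interferon median was -0.22 without background correction and -0.18 in the Z-scores and in the authors' values, and the matrix median was -0.28 without a filter on dim probes. The directional fry test, which does not compare a list with other genes, called 16 lists and its mixed version all 38.

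Other stress lists did not pass. Of 22 p53 targets, 2 rose and 9 fell (2 and 9 adjusted over the list alone; adjusted p = 0.096), with the death receptor TNFRSF10B at -1.03 ± 0.14 and SESN1, detected on 1 of the 3 knockout arrays, at -1.53 ± 0.17. The 40 tested genes nearest to TNFRSF10B and SESN1 had medians of -0.85 and -0.66. Of 29 genes of autophagy and the lysosome, 3 rose and 12 fell (3 and 13 adjusted over the list alone; adjusted p = 0.20), and the cysteine protease CTSB fell by 2.15 ± 0.20 and the cholesterol transporter NPC1 by 1.75 ± 0.18. Of 25 antioxidant genes, 5 rose and 6 fell (5 and 7 adjusted over the list alone; adjusted p = 0.39), with ferritin light chain FTL at -1.05 ± 0.15 and TKT at 0.82 ± 0.20. Endoplasmic reticulum chaperones had 3 rising and 1 falling of 16 (2 and 1 adjusted over the list alone; adjusted p = 0.39), with MANF up by 0.62 ± 0.15. Inflammatory genes had 4 and 4 of 18 (4 and 6 adjusted over the list alone; adjusted p = 0.92): IL32 rose by 2.65 ± 0.16 and the chemokine CCL2 by 2.19 ± 0.14, and IL1A was at least 1.65-fold lower. Hypoxia targets had 4 and 5 of 21 (4 and 5 adjusted over the list alone; adjusted p = 0.92), with PFKFB4 up by 0.68 ± 0.13. The genes that respond to handling had 4 rising and 5 falling of 21 (4 and 6 adjusted over the list alone; adjusted p = 0.41), with the immediate early genes FOS and EGR1 at -1.78 ± 0.22 and -1.68 ± 0.17 and KLF2 at 1.74 ± 0.15.

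DNA repair is the pathway of APTX itself. Of 26 genes of single-strand break and base excision repair, 3 rose and 6 fell (3 and 5 adjusted over the list alone; adjusted p = 0.92). XRCC1, the scaffold that binds aprataxin, fell by 0.63 ± 0.15, and with median centring it read -0.38, no longer past the threshold, or -0.64 relative to the median of all genes. Of 24 genes of double-strand break repair, 3 rose and 7 fell (3 and 7 adjusted over the list alone; adjusted p = 0.53), and the ubiquitin ligase RNF8 rose by 1.31 ± 0.18 where the 40 nearest genes had a median of 0.67. The G1/S list had 6 rising and 2 falling of 35 (5 and 2 adjusted over the list alone; adjusted p = 0.69), with RRM2 up by 1.47 ± 0.23, and G2/M had 9 and 2 of 40 (9 and 2 adjusted over the list alone; adjusted p = 0.33), with CCNB2 up by 0.74 ± 0.13 and CENPF at -1.09 ± 0.19. Of 55 cytosolic ribosomal protein genes, 3 rose and 3 fell (2 and 1 adjusted over the list alone; adjusted p = 0.96), with RPL7 at 0.74 ± 0.15 and RPL37, detected on 1 of the 3 knockout arrays, at -0.96 ± 0.20. This list shifted down in the Z-scores (adjusted p = 0.040). Cholesterol synthesis had 5 rising and 1 falling of 18 (6 and 1 adjusted over the list alone; adjusted p = 0.13), with CYP51A1 up by 0.98 ± 0.15 and MSMO1 by 0.91 ± 0.13. The 40 genes nearest to CYP51A1 had a median of 0.60.

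Markers of the bone lineage and of other cell types moved as well. Of 8 osteoblast lineage markers tested, 4 rose and 3 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.95): the matrix protein osteopontin, SPP1, fell by 4.16 ± 0.22 and collagen COL1A1 by 1.68 ± 0.13, while the growth factor BMP4 rose by 2.23 ± 0.19 and osteoprotegerin, TNFRSF11B, by 1.48 ± 0.16. The 40 genes nearest to BMP4 had a median of 0.52. Adhesion and cytoskeleton had 8 rising and 8 falling of 30 (8 and 8 adjusted over the list alone; adjusted p = 0.92), with MYL9 up by 1.74 ± 0.35, the integrin ITGA2 at -1.90 ± 0.19 and CD44 at -1.57 ± 0.13. Epithelial markers had 3 rising and 0 falling of 6 (3 and 0 adjusted over the list alone; adjusted p = 0.12): EPCAM rose by 1.41 ± 0.19, and the keratin KRT14 was at least 1.52-fold higher. Neuronal markers had 1 and 3 of 6 (3 and 3 adjusted over the list alone; adjusted p = 0.92), with the neurofilament NEFL at -1.16 ± 0.20 and its 40 nearest tested genes at a median of -0.72. Blood cell markers had 2 and 1 of 5 (2 and 1 adjusted over the list alone; adjusted p = 0.92), with CD34 at -2.15 ± 0.13. Median, mean and camera direction differed in sign for 9 lists, none of them past the threshold: fusion and fission, chaperones and proteases, glycolysis, fatty acid oxidation, inflammatory genes, cytosolic ribosomal proteins, adhesion and cytoskeleton, osteoblast markers and the region around APTX.

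**Figure D4:**
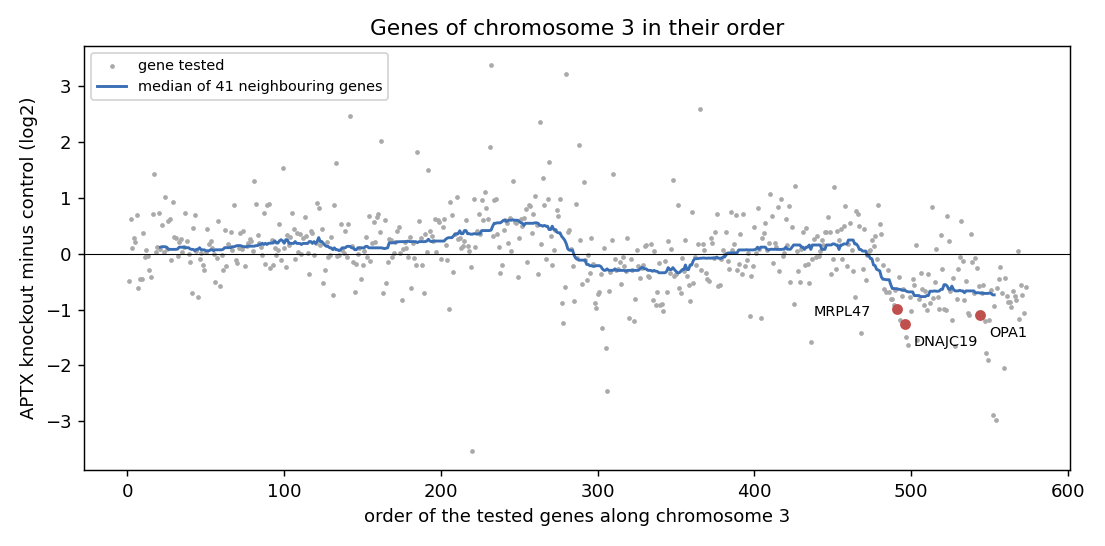
Difference between APTX knockout and control cells (log2) of the tested genes of chromosome 3 in their order along it, one grey point per gene, with the median of 41 neighbouring genes as a blue line. OPA1, MRPL47 and DNAJC19 (red) lie in the last stretch of the chromosome, where the 40 tested genes nearest to OPA1 have a median of -0.70.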

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

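Probes without a gene name entered no comparison between named genes, and some gave signal in the knockout arrays above that in the control arrays. The probe ILMN_1701905 was higher by 3.59 ± 0.16 on the log2 scale (8.46 ± 0.29 against 4.87 ± 0.08, SD, n = 3, limma adjusted p = 5.2e-07) and was at least 5.71-fold above the controls, where it was not well above background. The probe ILMN_1851610 was higher by 3.08 ± 0.19 (adjusted p = 3.4e-06), at least 4.33-fold. Of the unnamed probes that fell, ILMN_1782705 was at least 53.5-fold lower and ILMN_1674097 at least 53.3-fold lower. In all, 505 unnamed probes were higher and 475 lower in the knockout arrays.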

How the results depend on the processing

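All alternatives were chosen before the data were examined; the replicate block pairs samples by number, although the numbers were not seen to pair them. Single genes were not read against the size threshold of 1.2-fold. OPA1 was lower past the threshold in every alternative in which it was read, from -1.23 to -1.01 with 1 array left out (adjusted p 0.00086 to 0.0075) and -1.10 in the replicate block. APTX did not pass in any of these. It read 0.22 with median centring, or -0.04 relative to the median of all genes (0.26), and 0.0026 in Z-scores and 0.0046 in the authors' values, below the medians of all genes there (0.04 and 0.04). The number of genes changed was 2563 to 3556 with 1 array left out, 3059 in the replicate block, and 1884 (931 higher and 953 lower) against a threshold of 1.2-fold, which asks for more than a difference from 0. Genes changed at least 2-fold numbered 383 without background correction (191 higher, 192 lower), 645 with an offset of 50 (312 higher), 386 in Z-scores (212 and 174), 391 in the authors' values (217 and 174) and 579 among genes detected on all 6 arrays (273 and 306), where fewer genes were tested. Median centring called 678 genes lower, and 858 at least 2-fold higher and 309 lower. Otherwise the cause was not tested. Shifted lists numbered 6 without a filter, adding the tricarboxylic acid cycle and cholesterol synthesis (up) and p53 targets (down), 0 with an estimated correlation, 16 by directional fry and 38 by mixed fry. p53 targets also passed with the mean of all probes, and cholesterol synthesis without control replicate 1. A total was taken over 163 genes, those of the naming rule's first 3 parts and the others whose levels are given, without APTX and OPA1. Of 2890 values in 18 alternatives, 2715 kept direction and call, and 175 lost the call: 32 with median centring, and 26 each without knockout replicate 2 and without knockout replicate 3. Where detection on all 6 arrays was asked for, only 119 of the 163 genes had a value. Most of the 163 genes were chosen for being called in the main fit, which favours a high share of kept calls. Signal near background limits the dim probes: OPA1 read 178 to 257.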

Other observations

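The tests of gene families, copy number, close neighbours, OPA1 and short RNAs were chosen after the results they measure had been seen, as were the windows and the genes named here outside the rule, while the splits and the test of single arrays were chosen before. When the 160 symbol families with at least 8 tested members were compared by camera, 3 passed. The probes of all 9 GAGE genes tested fell, although they may share signal between near-identical copies, which the test counts as separate genes, with a median of -5.70 (adjusted p = 3.6e-13), or at least 30.5-fold with these genes at their bounds, since none was well above background in the knockout cells. Of 8 small Cajal body RNA genes, which guide the modification of spliceosomal RNAs, 7 rose, with a median of 2.09, or 1.37 with 3 genes at their bounds (adjusted p = 9.8e-06), among them SCARNA11 at 3.26 ± 0.16 and SCARNA13 at 2.48 ± 0.13. Of 26 SNORD genes 16 rose and 2 fell (adjusted p = 0.0045). With an estimated correlation none of the 3 held (camera adjusted p = 0.61, 0.61 and 0.98). That estimate rests on 6 arrays, so a call lost there is not evidence that a family did not shift. The direction of the GAGE and SCARNA medians was kept in each of the 6 scalings, where the GAGE median lay between -5.70 and -3.83 and the SCARNA median between 0.89 and 2.14.

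Differences also followed chromosome order. In windows of 41 tested genes, the lowest median was -1.04, around ATP6V1B2 on chromosome 8, where 32 genes fell and 0 rose. Windows around WDR13 on chromosome X (33 lower and 0 higher, with GAGE12G as its last gene), RAP2A on chromosome 13 (34 and 1) and MAP6D1 on chromosome 3 (32 and 2) had medians of -0.88, -0.88 and -0.77. The highest medians were 0.73 around JMY on chromosome 5 (33 higher and 0 lower) and 0.70 around MTCH1 on chromosome 6 (28 and 0). These medians kept their direction in the 6 scalings but changed in size. They were -1.04 to -0.61 around ATP6V1B2, -0.88 to -0.61 around WDR13, -0.88 to -0.52 around RAP2A and -0.77 to -0.51 around MAP6D1. The windows around JMY and MTCH1 had 0.60 to 0.98 and 0.58 to 0.95. Genes of the report whose 40 nearest tested genes had a median at least 0.5 from 0 in the gene's own direction included OPA1 (-0.70), TIMM17B (-0.87), TNFRSF10B (-0.85), NEFL (-0.72), SESN1 (-0.66), DNAJC19 (-0.65), MRPL47 (-0.63), PHB2 (-0.60), SLC2A3 (-0.59), GAGE12B (-0.58) and GAGE12G (-0.50) among those that fell, and MTX3 (0.73), RNF8 (0.67), MRPS27 (0.65), CYP51A1 (0.60), TOMM6 (0.56), BMP4 (0.52) and NAMPT (0.50) among those that rose. Smaller medians in the gene's own direction were seen for further genes. Among genes that fell they included those of CTSB (-0.49), ATP5MC2 (-0.47), CENPF (-0.46), DDIT3 (-0.44), TBK1 (-0.41), BCL2L13 (-0.35), FTL (-0.33), XRCC1 (-0.30) and CD34 (-0.27). Among genes that rose they included those of IL17RB (0.42), UQCR11 (0.41), RPL7 (0.40), TKT (0.38), DLD (0.34), MTFR1 (0.34) and CCNB2 (0.33). GPC5, SCARNA11 and SLC7A10 rose where the 40 nearest genes had medians of -0.76, -0.53 and -0.41. COL6A3 and IL1A fell where the nearest genes had medians of 0.49 and 0.34. The genes nearest to APTX had a median of 0.01.

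Copy number differences between the knockout and the control cells are a candidate explanation of this order. Among genes changed less than 2-fold, the differences of genes 40 positions apart had a rank correlation of 0.0735, above the highest of 1000 shuffles of gene order (0.038); over all genes it was 0.108 (highest shuffle 0.031). Shared control limited to neighbours fewer than 40 positions apart is argued against as the whole cause by that value, while control over longer stretches was not tested and stays open. The correlation was 0.250 for adjacent genes, 0.0310 at 80 positions and 0.00419 at 120; these are correlations across genes, which are not independent replicates. A bias of single arrays that follows position is argued against by the dimmest array, since control replicate 1 against the other controls gave -0.011 (highest shuffle 0.040), but a position bias shared by all arrays of a group cannot be excluded, and no DNA was measured here.

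The lower OPA1 signal lies within one of these stretches. The 40 tested genes nearest to OPA1 had a median of -0.70, below the 5th percentile (-0.14) and the lowest (-0.29) of 1000 random sets of 40 genes, and 37 of them were below 0; among all 9084 windows of 41 genes, 1.43% had a median as low. OPA1 itself fell by 1.10, and 9 of the 40 neighbours fell at least as far, among them APOD and MUC4, at least 2.86-fold and 3.37-fold lower. A loss of copies of the end of chromosome 3 in the knockout cells may thus account for part or all of the OPA1 fall, as a hypothesis not tested on DNA, and an effect of APTX loss on OPA1 itself stays open beside it, untested. Background correction as the whole cause is argued against, since without it the difference was -0.56 with a limma adjusted p of 0.0017. Over all alternatives the adjusted p of OPA1 was 0.00023 to 0.0075. Most of these keep the background correction, so that range does not bear on this cause.

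Of 53 small nucleolar RNA genes 27 rose and 4 fell, with a median of 0.50, which was between 0.23 and 0.67 in the 6 scalings. For this class the camera p, not adjusted for the families compared above, was 7.5e-06, and 0.013 with an estimated correlation. Among those families SNORA did not pass, with 11 of 26 genes higher and 2 lower (camera adjusted p = 0.081). With an estimated correlation the camera adjusted p was 0.98 for SNORD and for SNORA. Signal shared between copies of the same numbered family was examined with 1 gene kept per numbered family. That kept 47 of the 53 genes, and the camera p at the preset correlation was 4.8e-06. Since so few genes were dropped, this p could hardly have changed, and the test does not decide on shared signal. Families were also told apart by symbol and not by sequence, so shared signal stays open. More short RNA carried through the RNA preparation of the knockout samples could not be told apart from a change in the cells. Labelling was from an oligo-dT primer, and whether these probes read the short RNAs themselves or longer transcripts was not tested. The 10 other short structural RNAs tested, without the small Cajal body RNA genes (median 2.09), had a median of 0.45 (SD 0.50, and 0.28 to 0.68 in the 6 scalings). That lay below the median of the small nucleolar RNAs here and above it in the other 5 scalings. Of these 10, 4 rose, among them RNVU1-7 at 0.93, and 1 fell, the RNase P RNA RPPH1 at -0.63, a call lost without background correction (-0.26), with median centring (-0.48), in Z-scores (-0.23), in the authors' values (-0.23), and without knockout replicate 2 (-0.46) or control replicate 3 (-0.60).

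Other splits of the 6 arrays into 3 and 3 are too few (10 in all) for a share under 0.05. The real split gave 3733 changed genes and 991 changed at least 2-fold, each in 1 of the 10 splits. The highest of the other splits gave 0 and 0. Each of the other splits mixes knockout and control arrays on each side. The group difference then adds to the spread within each side, so counts of 0 there say little about chance. The real split gave 3 shifted gene lists, and 4 of the 10 splits, the real one included, gave at least as many, the highest of the others 4. Part of the group difference remains in the mixed splits, so their list counts are no clean measure of chance either.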
